A study of Mus musculus with 9 samples.

How the data were processed

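Lungs of wild-type mice were profiled by droplet single-cell RNA sequencing. The series held 9 libraries, namely 3 from control mice and 6 from mice given diquat, a bipyridyl herbicide that cycles between redox states and produces superoxide. The diquat libraries carried the letters D and E in their titles, 3 libraries each, and are called set D and set E here. Dose, time after exposure and the difference between the lettered sets were not given in the labels. The set D libraries carried another code prefix than the control and set E libraries, so any handling difference behind that prefix cannot be separated from the set. Nothing in the labels said that the libraries came from separate animals, so p-values measure the spread between these libraries, which may be technical.

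Cells were captured with barcoded gel beads in oil droplets, and the barcoded cDNA was amplified, fragmented and made into sequencing libraries, per the labels' protocols. Seurat and the mouse build mm10 were named in the submitters' processing notes, without versions. The aligner and the gene annotation were not given in the sources used here. The authors deposited a single matrix of natural log values for 24313 genes and 72838 cells, each column carrying its library code. The values themselves showed how they were made, since back-transformed values summed to 10000 in each cell, which is the natural log of 1 plus the UMI count (unique molecular identifiers, a count of captured molecules) divided by the cell total and multiplied by 10000. Dividing by the smallest value of each cell returned whole UMIs for 100% of nonzero values within a tolerance of 0.01. Cells held 501 to 4997 detected genes and at most 9.99% mitochondrial UMIs, so cells had been filtered before deposit, and the cell filter fixed for this work (at least 200 genes, at most 25% mitochondrial UMIs) removed 0 cells. UMIs per cell ran from 599 to 29838 with a median of 4042.

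The tests fixed before the data were examined assumed raw counts, with limma on mean values as the stated replacement should the matrix hold log values. The matrix held natural logs, so that replacement was used. For each library and cell class the mean natural log value of each gene was taken over cells, and limma 3.58.1 (R 4.3.3) was fitted to these means with an empirical Bayes trend over all 3 groups. The diquat comparison was the mean of set D and set E minus control, and the set comparison was set D minus set E. A gene was tested in a class when at least 10% of its cells held a UMI in at least 3 libraries, and p-values were adjusted by the Benjamini-Hochberg method over the genes of a class with a threshold of 0.05. A library entered a class with at least 30 cells, and the 8 most abundant classes with enough libraries were tested. Clustering at resolution 1.0 named 12 cells of control 1 and 19 of set D 1 as classical monocytes, so both were left out of that class. At resolution 2.0 control 1 held 485 classical monocytes, and its nonclassical monocytes numbered 214 in place of 677. Alveolar fibroblasts and interstitial macrophages lacked set D 1.

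The summed UMIs recovered from the values gave CPM (UMIs scaled to a common total) per library and class, and limma was also fitted to log2 CPM with a prior count of 1. Fold changes and their standard errors in the text are on this log2 CPM scale. Simulated cells with 200 changed genes were drawn at the median depth of each library in a class, with at most 150 cells per library. All simulated libraries shared a mean profile, and their spread was estimated without control 1. Every gene was given the same spread between libraries. Cells of a library shared the same depth and profile and differed by random sampling alone. The rates below therefore do not cover the deviation of control 1 from the other libraries. Nor do they cover genes that vary more than others, or classes whose clusters are mixed differently between libraries, where false calls may be more frequent. At the real depths the mean natural log test made too many false calls. Over 4 simulated data sets, 14.8% of its calls in neutrophils (3840 genes on average) and 9.97% in adventitial fibroblasts (6670 genes) were false, and it called 12.2 and 2.75 genes on average in the set comparison, where none had been changed. The share of false calls was 7.41% and 6.43% with equal depths. The log2 CPM test gave 3.91% and 3.61% false calls and 0 set calls at the real depths, and genes past both tests in the same direction gave 1.45% and 1.69% and 0 set calls. With equal depths the log2 CPM test gave 7.09% and 4.01% and both tests together 4.76% and 1.48%. A gene past both tests at the real depths was recovered in neutrophils and adventitial fibroblasts in 5.06% and 2.92% of cases for a 1.5-fold change, in 31.5% and 23.4% for a 2-fold change, and in 96.2% and 93.9% for a 4-fold change. The mean natural log counts were kept as the stated result. The words rose, fell and changed are used for single genes only where both tests passed in the same direction, a rule set from the simulation after the data had been seen.

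Cells were clustered without integration of libraries in scanpy 1.11.5, with 2000 variable genes chosen across libraries, scaling with values capped at 10, 30 principal components, 15 neighbours and Leiden resolution 1.0 (leidenalg 0.10.2, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). Cluster names rest on marker lists fixed before the data were examined, and every name means cells like that type by markers. The naming rule was set after the clusters were seen. It asked for a marker score of at least 0.9, at least 3 markers each detected in at least 10% of the cells, and at least 100 cells, and it left a cluster unnamed when its top 10 genes held more markers of another class. Clusters of T-lineage cells with over 95% of their cells from set D 1 and set D 2 were kept out of the T cell class, and their shares are given. The doublet caller Scrublet, run on the recovered UMIs, marked 0.183% of cells, under the 0.5% below which such a caller has not worked, so no cell was removed as a doublet.

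Shares of 19 named classes were taken over all cells of a library and compared by an exact two-sided permutation test. It allowed 84 splits of 6 diquat and 3 control libraries, with a smallest p of 0.0119, and a smallest p of 0.10 for set D against set E. Gene lists fixed before the data were examined covered 21 themes. They were NRF2 targets, p53 targets, acute inflammatory cytokines and chemokines, the interferon response, the glucocorticoid response, the unfolded protein and integrated stress response, heat shock, immediate early genes, hypoxia and glycolysis, iron and ferroptosis, cell division, extracellular matrix and fibrosis, the transitional alveolar epithelial state, surfactant and lamellar body, MHC class II presentation, mitochondrially encoded transcripts, nuclear oxidative phosphorylation, endothelial activation, platelet transcripts, and free RNA in lists of haemoglobin, surfactant and club genes and of granulocyte and immunoglobulin genes. Lists with at least 3 measured members were tested with limma's camera on the mean natural log values with a preset correlation of 0.01, adjusted over the 130 tests of a comparison. Mean natural log values replaced the planned voom weights before list results were viewed, and camera with voom and with log2 CPM stands beside it.

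Named genes followed a rule fixed before the data were examined. In each class and comparison these were up to 3 rising and 3 falling genes with the largest change among those past the threshold of the mean natural log test, with at least 50 CPM on the higher side and every library of one side above every library of the other, with the same sign on both scales. Up to 4 members with the smallest adjusted p were also named from each called list, and the 2 genes with the smallest p where none passed. Immunoglobulin and T-cell receptor segments, haemoglobin, ribosomal protein, mitochondrially encoded (outside their list) and sex-linked marker genes and unnamed gene models were left out. A few genes that this rule names are not reported here. Gene positions are those of annotation vM21 on GRCm38 (mm10), matched by symbol for 175 of the 178 named genes. The annotation behind the matrix is not known, so positions describe the gene and not the counted reads. Alternatives covered filters, cluster resolution, thinning, scaling, tests, each library left out in turn, the replicate number as a block and each diquat set alone. Figures were drawn with matplotlib 3.10.9.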

Results

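Single-cell transcriptomes of mouse lung were compared between 3 control libraries and 6 libraries from mice given diquat, 3 in set D and 3 in set E, to ask which cell types and genes change when the lung is injured by this pesticide. Control libraries 1, 2 and 3 held 9139, 7339 and 9050 cells with 53463938, 49762459 and 57082113 UMIs. Set D libraries held 12714, 8689 and 9240 cells with 40741457, 39395956 and 45604203 UMIs, and set E libraries 6306, 4863 and 5498 cells with 33978456, 36915648 and 39161073 UMIs. Median UMIs per cell were 5182, 4822 and 4765 in controls, 2622, 3248 and 3310 in set D and 4539, 5944 and 5266.5 in set E, so set D was the shallower group per cell. Clusters were named by markers into 19 classes, each name meaning cells like that type. Values are means ± SD over libraries in CPM (UMIs scaled to a common total) or percent of cells, with n = 3 per group. In classical monocytes, where clustering at resolution 1.0 left control 1 with 12 cells, n = 2 for controls and set D, and in alveolar fibroblasts and interstitial macrophages n = 2 for set D.

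Natural killer cells, the cytotoxic innate lymphocytes, and nonclassical monocytes, which patrol the vessel wall, formed smaller shares of the cells in all 6 diquat libraries than in any control library. Natural killer cells made up 5.05% ± 0.410 of control cells, 1.81% ± 1.62 in set D and 0.726% ± 0.569 in set E. Nonclassical monocytes made up 5.15% ± 1.99 of control cells, 0.0821% ± 0.0512 in set D and 0.632% ± 0.291 in set E. The differences of -3.78 and -4.79 percentage points each had an exact two-sided permutation p of 0.0119, the smallest that the 84 splits allow, and an adjusted p of 0.113 over 19 classes. By that test 0 of 19 classes passed, 2 had an unadjusted p under 0.05, and limma on log-odds of the shares called 1, nonclassical monocytes (adjusted p = 0.00318). Cells under 501 genes were absent from the matrix, and shares also depend on dissociation and on the lower depth per cell of set D. At resolution 2.0 control 1 held 214 nonclassical monocytes (2.34% of its cells) in place of 677 (7.41%), and the difference was -3.14 percentage points with the same adjusted p of 0.113 by the exact permutation test.

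**Figure D1:**
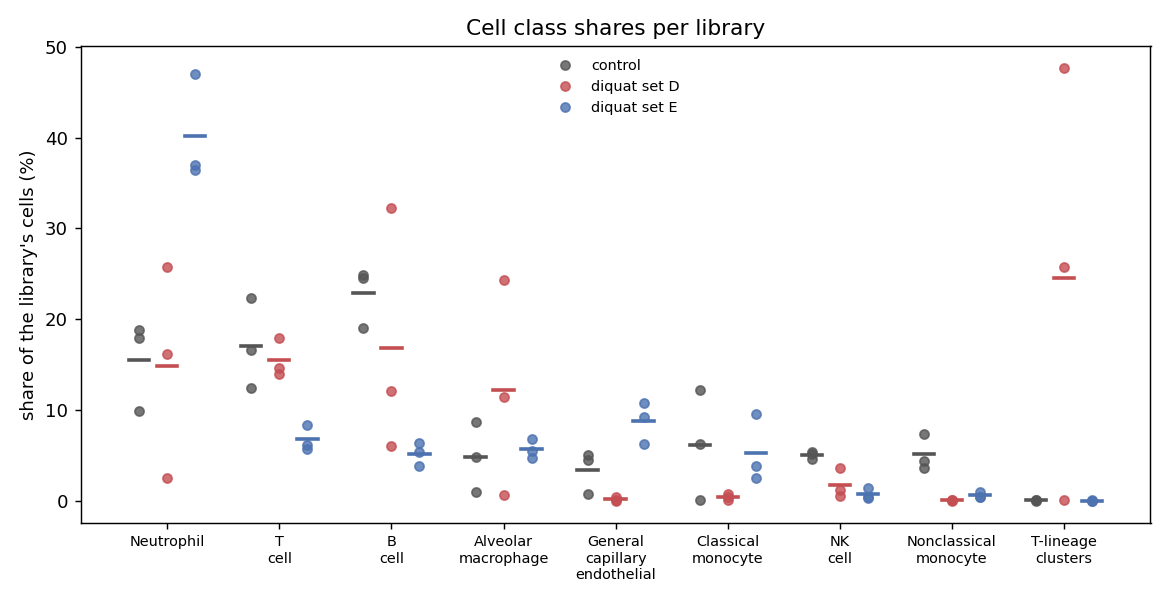
Share of all cells (percent, vertical axis) held by named cell classes in each of the 9 libraries, with 1 point per library grouped as control, set D and set E, and the share of the T-lineage clusters kept out of the T cell class. Natural killer cells and nonclassical monocytes lie lower in all 6 diquat libraries than in the controls, and the T-lineage clusters reach 47.7% and 25.8% in set D 1 and set D 2.

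The list of glucocorticoid response genes was called higher with diquat in all 8 tested classes by limma's camera. With an estimated correlation 0 of these calls held, the lowest being an adjusted p = 0.0529 with an estimated correlation. Fkbp5, a co-chaperone of the glucocorticoid receptor (chromosome 17, 28399094 to 28517527, minus strand, protein-coding, GRCm38), went from 19.2 ± 3.79 CPM in control interstitial macrophages to 352 ± 126 in set D and 281 ± 110 in set E, a log2 change of 3.94 ± 0.31 (SE). It also rose in neutrophils (3.07 ± 0.42), alveolar macrophages (2.07 ± 0.19), alveolar fibroblasts (3.11 ± 0.29), classical monocytes (3.36 ± 0.30) and adventitial fibroblasts (1.59 ± 0.34). In T cells and B cells its log2 changes of 1.45 ± 0.26 and 2.27 ± 0.40 missed the threshold, with limma adjusted p of 0.143 and 0.168. Every diquat library lay above every control for Fkbp5 in 7 of the 8 classes, the exception being adventitial fibroblasts, where control 1 held 107 CPM and set E 3 held 100.4. In alveolar macrophages, interstitial macrophages and classical monocytes Fkbp5 was named among the largest changes. The naming rule asks for this separation, so there it is no separate result.

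**Figure D2:**
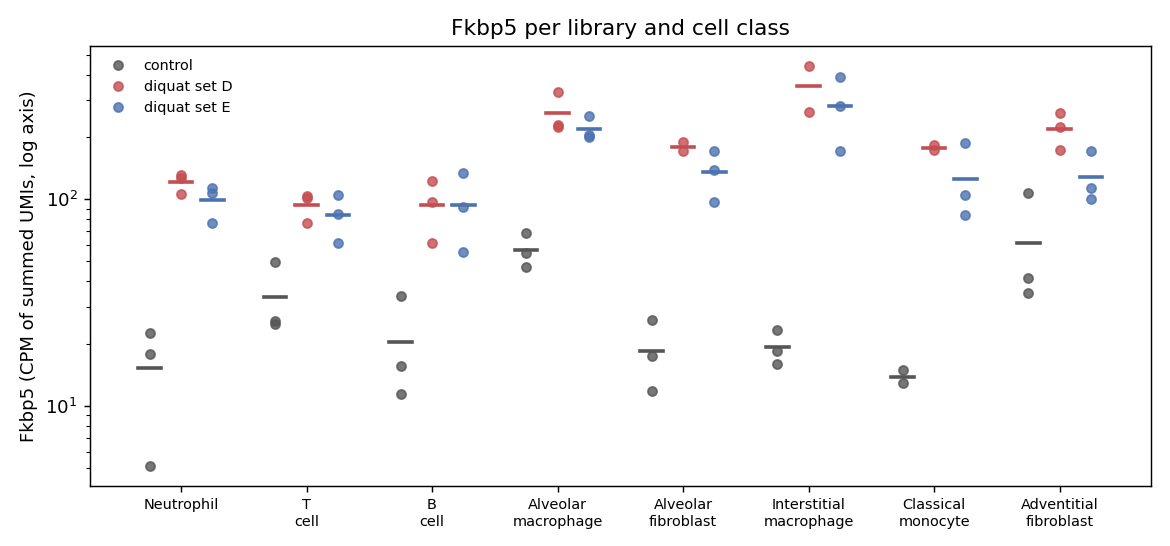
Fkbp5 in CPM of the summed UMIs of a class (vertical log axis) for each library in the 8 tested classes, with 1 point per library coloured as control, set D or set E. In interstitial macrophages the controls lie between 15.9 and 23.4 CPM and the diquat libraries between 170.1 and 441.

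The glucocorticoid list was called higher by limma's camera in 8 of 8 classes and in 7 on all 3 scales. In adventitial fibroblasts 11 of its 12 measured members passed the mean natural log test, 10 of these also passed on log2 CPM, and 12 passed adjusted over the list alone. They included Mt1, a metal-binding metallothionein, at 822 ± 213 CPM in controls, 6747 ± 3517 in set D and 7721 ± 3717 in set E, and Tsc22d3, a glucocorticoid-induced leucine zipper protein (chromosome X, 140539528 to 140600659, minus strand), at 85.2 ± 25.1, 1077 ± 426 and 760.4 ± 153 CPM. In alveolar fibroblasts 6 of 11 members rose by both tests and 11 did adjusted over the list alone, in neutrophils 4 of 11 (Fkbp5, Mt1, Tsc22d3 and Klf9) and 8, and in interstitial macrophages 3 of 11 and 9. In classical monocytes 2 of 11 rose by both tests, with 6 higher and 1 lower adjusted over the list alone, and in alveolar macrophages 1 of 10 rose and 8 passed over the list alone. In T cells 0 of 7 and in B cells 0 of 4 members passed over all genes by limma on either scale except Ddit4 in T cells on log2 CPM, with 4 and 2 adjusted over the list alone. With an estimated correlation no class kept the call, from an adjusted p = 0.0529 with an estimated correlation in adventitial fibroblasts to an adjusted p = 0.514 in B cells, by limma's camera. The B cell call also had an adjusted p = 0.142 on log2 CPM. It ended without set D 2 or set D 3 (limma adjusted p = 0.0566 and 0.0663).

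The list of interferon response genes was called lower with diquat in 4 classes by limma's camera, and in 0 with an estimated correlation, the lowest being an adjusted p = 0.0529 with an estimated correlation. Ifi27l2a, an interferon-induced membrane protein (chromosome 12, 103442167 to 103443680, minus strand), fell from 1855 ± 531 CPM in control neutrophils to 479 ± 162 in set D and 156 ± 75.0 in set E, a log2 change of -2.82 ± 0.36. Isg15, a ubiquitin-like modifier, fell from 876 ± 273 to 264 ± 88.5 and 164 ± 23.3 CPM, and Rtp4 and Oasl2 fell with log2 changes of -1.90 ± 0.29 and -1.58 ± 0.24. Of 10 measured members 7 were lower by the mean natural log test, 4 by both tests and 10 adjusted over the list alone (limma camera adjusted p = 3.00e-10, adjusted p = 0.0529 with an estimated correlation). In classical monocytes 8 of 16 were lower by the mean natural log test, 1 by both tests (Ifi27l2a, log2 change -1.74 ± 0.27) and 16 adjusted over the list alone, with an adjusted p = 0.214 with an estimated correlation. The call in interstitial macrophages was the one not kept on all 3 scales (limma adjusted p = 0.0821 on log2 CPM). In alveolar fibroblasts 0 of 12 and in interstitial macrophages 0 of 12 passed both tests, with 5 and 1 adjusted over the list alone, and for both calls limma's camera gave an adjusted p = 0.619 with an estimated correlation. Leaving out control 3 ended both of these calls (limma adjusted p = 0.242 and 0.210). Leaving out set D 3 ended the macrophage call (limma adjusted p = 0.0523).

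In neutrophils Pik3ip1, an inhibitor of phosphoinositide 3-kinase, rose from 3.09 ± 1.36 CPM in controls to 102 ± 25.8 in set D and 80.8 ± 57.8 in set E (log2 change 4.80 ± 0.47). Mt1 (chromosome 8, 94179082 to 94180327, plus strand) rose from 12.4 ± 6.61 to 525 ± 99.2 and 92.6 ± 46.5. Prnp, the prion protein, rose from 5.20 ± 2.99 to 68.2 ± 19.9 and 62.6 ± 15.97 CPM. Oasl1, an interferon-induced protein, fell from 95.9 ± 57.5 to 18.3 ± 5.92 and 8.72 ± 2.84. Slfn5 measured 178 ± 63.2, 49.1 ± 40.8 and 16 ± 8.29 CPM and missed the log2 CPM test (limma adjusted p = 0.0540). Of 3525 genes tested, limma called 109 (39 higher, 70 lower) on mean natural log values and 75 (50 higher, 25 lower) on log2 CPM, and 34 rose and 24 fell by both. The neutrophil clusters held different libraries, since 1630 cells of a cluster of 1635 came from control 1 and most cells of another came from set E. In the latter cluster Il23a, Cxcl3 and Cxcl2 were among the top 10 genes. The mean natural log count was 22 without set D 1 and 418 without control 3, and Pik3ip1 missed the threshold without control 1 (limma adjusted p = 0.0517).

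In interstitial macrophages Ddit4, a stress-induced inhibitor of mTOR, rose from 4.08 ± 3.56 CPM in controls to 227 ± 51.5 in set D and 134 ± 74.0 in set E (log2 change 5.71 ± 0.78). Mgl2, a C-type lectin (chromosome 11, 70130329 to 70137550, plus strand), fell from 560.5 ± 107 to 107 ± 42.1 and 121 ± 19.8. In alveolar macrophages Ap1s2, a clathrin adaptor subunit, rose from 77.3 ± 9.03 to 587 ± 87.2 and 343 ± 108 CPM (log2 change 2.51 ± 0.22). In classical monocytes Crispld2, a secreted protein, rose from 1.30 ± 0.501 to 79.0 ± 4.26 and 47.7 ± 19.2 CPM. Il1r2, the decoy receptor of interleukin 1, rose from 9.69 ± 6.98 to 309 ± 177 and 311 ± 259. Tppp3, a tubulin-binding protein, fell there from 168 ± 2.63 to 8.74 ± 4.62 and 30.5 ± 12.04 CPM (log2 change -3.43 ± 0.37, limma adjusted p = 9.86e-05). Passing the mean natural log test alone were Pla2g2d, Ccnd1 and 7SK.197 in interstitial macrophages, Ear6, Hivep3 and Fgr in alveolar macrophages and Lars2 and Hes1 in monocytes, with Ccnd1 at 336 ± 97.6, 80.8 ± 16.2 and 53.9 ± 33.8 CPM. Limma called 36 of 7014 genes (14 higher, 22 lower) in interstitial macrophages, against 48 (40 and 8) on log2 CPM and 20 (13 and 7) by both. In alveolar macrophages it called 11 of 8274 (7 and 4), against 23 (22 and 1) and 5 (5 and 0). In monocytes it called 83 of 7003 (19 and 64), against 12 (10 and 2) and 12 (10 and 2). Without control 1 the mean natural log counts were 170 and 209 in the macrophage classes. Left-out libraries took them down to 0 (set D 2 or set D 3, either of which leaves 1 set D library) and 2 (control 2 or set E 3). The monocyte count was 18 without control 2 and 149 without set D 2. At resolution 2.0, where control 1 entered the class with 485 cells, it was 38, and Il1r2 and Lars2 missed the threshold.

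Angptl4, a secreted inhibitor of lipoprotein lipase (chromosome 17, 33773750 to 33781830, minus strand), rose in alveolar fibroblasts from 47.9 ± 29.2 CPM in controls to 636 ± 48.7 in set D and 606 ± 228 in set E, and in adventitial fibroblasts from 21.3 ± 3.48 to 342 ± 51.2 and 273 ± 111 (log2 changes 3.82 ± 0.40 and 3.74 ± 0.25). Pdk4, a kinase that inhibits pyruvate dehydrogenase (chromosome 6, 5483351 to 5496309, minus strand), rose in alveolar fibroblasts from 10.8 ± 5.94 to 189.6 ± 39.5 and 125 ± 62.2 CPM. Fabp4, a fatty acid-binding protein, rose in adventitial fibroblasts from 14.4 ± 7.18 to 385 ± 182 and 202 ± 115 CPM. Gja5, a connexin, fell in alveolar fibroblasts from 53.04 ± 21.2 to 5.67 ± 2.47 and 9.65 ± 3.07 CPM. Lars2, the mitochondrial leucyl-tRNA synthetase, fell in adventitial fibroblasts from 1086 ± 276 to 315 ± 241 and 129 ± 39.6. Rn18s-rs5, a ribosomal RNA sequence chosen here after its values were seen, was like Lars2 highest in control 2 and, within set D, in set D 2. Over all cells Rn18s-rs5 was at 95170 and 35380 CPM in controls 2 and 3, at 2764, 35180 and 6054 in set D and at 758, 8289 and 7577 in set E. Control 1 held no UMI under this symbol but 35710 CPM under Gm42418, a symbol also chosen after its values were seen and with no UMI in the other libraries. Lars2 in adventitial fibroblasts was at 1148, 1326 and 785 CPM in controls, 159, 592 and 194 in set D and 83.6, 149.8 and 154 in set E. Fgfr4, Gfra2 and Pals2 in alveolar and Pals2, Tmem132c and St8sia2 in adventitial fibroblasts passed the mean natural log test alone, and Pals2 had no UMI in control 1. Limma called 59 of 8479 genes (30 higher, 29 lower) in alveolar fibroblasts, against 87 (63 and 24) on log2 CPM and 43 (25 and 18) by both. In adventitial fibroblasts it called 116 of 6848 (73 and 43), against 132 (87 and 45) and 83 (60 and 23). The alveolar count was 0 without control 2 or set D 3, the latter leaving 1 set D library, and 295 without set E 1. The adventitial count was 19 without control 2 and 180 without control 1, where 93 of the 116 genes were shared.

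In T cells Ms4a4c, Cd55, which shields cells from complement, and Dtx1, a regulator of Notch signalling, fell with log2 changes of -1.36 ± 0.21, -1.33 ± 0.18 and -1.32 ± 0.15. Dtx1 went from 68.4 ± 6.09 CPM in controls to 23.1 ± 3.96 in set D and 32.7 ± 3.29 in set E. Limma called 4 of 5342 genes (0 higher, 4 lower) on mean natural log values, against 20 (16 and 4) on log2 CPM and 3 lower by both. The mean natural log count was 39 without control 1. In B cells limma called 0 of 4041 genes, with 724 at an unadjusted p under 0.05, and 1 on log2 CPM. The B cell genes with the smallest p were Rbm3, a cold-inducible RNA-binding protein, at 266 ± 50.9, 976 ± 192 and 791 ± 278 CPM, and Calr, the chaperone calreticulin, at 316 ± 21.0, 184 ± 46.6 and 128 ± 17.7, both at a limma adjusted p = 0.0780. The B cell count was 21 without control 1 and 27 without control 3. Cells of control 1 formed T cell and B cell clusters of their own, and 3601 of 4240 cells of another B cell cluster came from set D 1.

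The remaining lists gave fewer single genes. NRF2 targets, the antioxidant defence genes, were called higher in interstitial macrophages, where 1 of 17 rose by both tests (Hmox1, haem oxygenase, 160 ± 29.7 CPM in controls, 452 ± 56.4 in set D and 1298 ± 864 in set E) and 6 adjusted over the list alone, with an adjusted p = 0.122 with an estimated correlation (limma). In alveolar macrophages they were called higher with 0 of 16 past both tests, 12 adjusted over the list alone and an adjusted p = 0.453 with an estimated correlation. The unfolded protein list was called lower in adventitial fibroblasts, where 1 of 11 fell by both tests (Hsp90b1, an endoplasmic reticulum chaperone, log2 change -1.03 ± 0.16) and 6 adjusted over the list alone, with an adjusted p = 0.453 with an estimated correlation (limma). It was called higher in neutrophils, where 0 of 8 passed and 1 did adjusted over the list alone, with an adjusted p = 0.619 with an estimated correlation (limma). Inflammatory cytokines were called higher in neutrophils (0 of 13) and monocytes (0 of 16) and lower in alveolar macrophages (0 of 14), with 1 member adjusted over the list alone in each and an adjusted p = 0.619, 0.619 and 0.749 with an estimated correlation. The call in monocytes ended without control 2 (limma adjusted p = 0.673). That in alveolar macrophages ended without control 1 or set E 1 (limma adjusted p = 0.642 and 0.152). Immediate early genes were called higher in neutrophils, T cells and B cells with 0 members past either adjustment of the mean natural log test. Mitochondrially encoded transcripts were called lower in alveolar macrophages with 2 of 13 adjusted over the list alone. There mt-Atp8 was at 321.3 to 410.9 CPM in controls and 92.14 to 229.1 in diquat libraries. In contrast mt-Nd1 ran against the call, at 2196 to 2308 in controls and 2410 to 3228 in diquat libraries. The transitional epithelial list was called higher in both fibroblast classes and interstitial macrophages with 1, 3 and 1 adjusted over the list alone. It was kept on all 3 scales in alveolar fibroblasts, but not in adventitial fibroblasts or interstitial macrophages (limma adjusted p = 0.0746 and 0.0602 on log2 CPM and 0.0758 and 0.0574 with voom). With an estimated correlation these calls had an adjusted p = 0.190 or above by limma's camera. Without control 1 the immediate early calls ended (limma adjusted p = 0.0727, 0.284 and 0.686), as did the mitochondrial call (limma adjusted p = 0.566). The B cell call also ended without control 2 (limma adjusted p = 0.0525). The transitional call ended in adventitial fibroblasts without control 2 (limma adjusted p = 0.0873). In interstitial macrophages it ended without control 1, set D 2 or set E 3 (limma adjusted p = 0.372, 0.0860 and 0.0506). Of 130 tests 26 were called, 22 on all 3 scales and 0 with an estimated correlation (15 had an unadjusted p under 0.05). Lists with no call had smallest adjusted p-values by limma's camera of 0.0672 (nuclear oxidative phosphorylation), 0.0713 (iron), 0.104 (MHC class II, hypoxia and p53), 0.113 (extracellular matrix), 0.122 (cell division), 0.161 (heat shock), 0.285 (surfactant), 0.435 (endothelial activation) and 0.460 (granulocyte and immunoglobulin RNA), and the haemoglobin, surfactant and club list and the platelet list had under 3 measured members in every class.

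**Figure D3:**
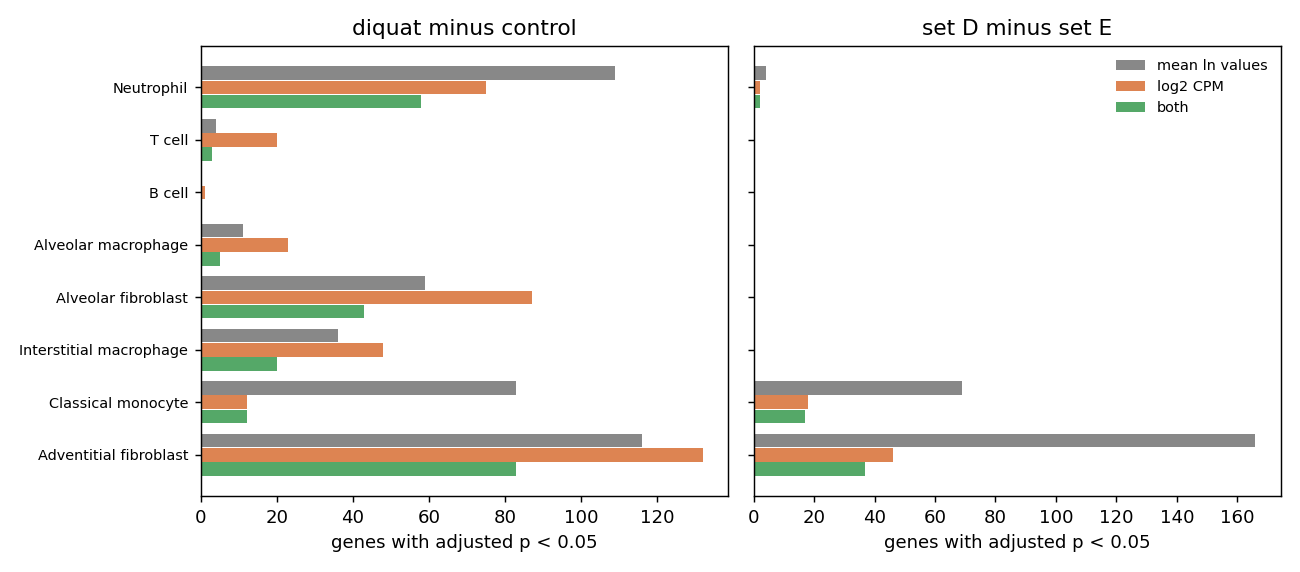
Number of genes with an adjusted p under 0.05 (horizontal axis) in each tested class, in panels for diquat minus control and for set D minus set E, by the tests shown in the legend. With diquat, adventitial fibroblasts gave 116 genes and B cells 0 by the mean natural log test.

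Control 1 stood apart from the other libraries in the classes where it was tested. Its median Pearson correlation with the others over mean natural log values was 0.80 to 0.879, against 0.91 to 0.982 for the other libraries, and 153 genes of at least 10 CPM in each of the other 8 libraries had no UMI there. Pals2 in both fibroblast classes, 7SK.197 in interstitial macrophages and Serpina3m in adventitial fibroblasts were among the named genes at 0 in control 1. Mpp6, the older symbol of Pals2 and chosen after its values were seen, was at 55.4 CPM over all cells of control 1 and at 0 in the other libraries.

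**Figure D4:**
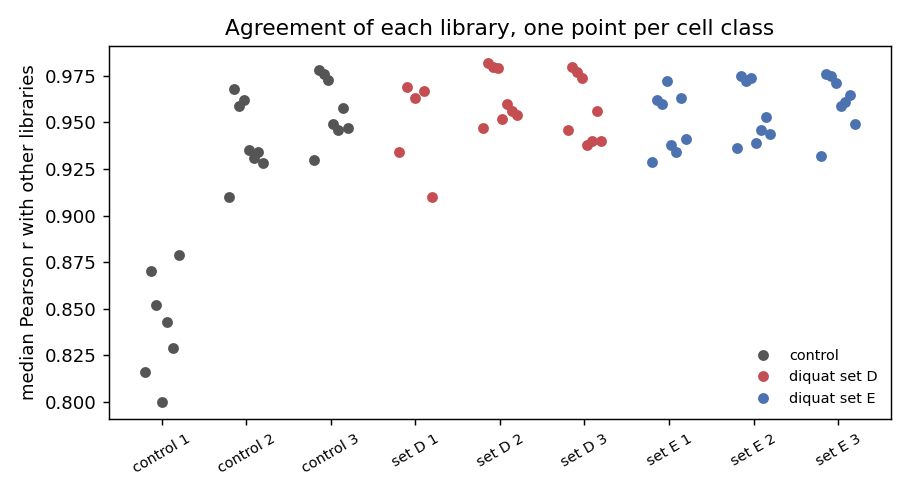
Median Pearson correlation r of each library with the other libraries over the genes tested (vertical axis), with 1 point per cell class for each library. Control 1 lies between 0.80 and 0.879 and the other libraries between 0.91 and 0.982.

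The labels give both lettered diquat sets the same treatment term, and the comparison of set D with set E asks how far they differ. In classical monocytes Il1b, the cytokine interleukin 1 beta (chromosome 2, 129364570 to 129371139, minus strand), measured 731 ± 109.9 CPM in set D and 4669 ± 706 in set E (controls 2022 ± 569), a log2 difference of -2.67 ± 0.25 (limma adjusted p = 0.000559). Cxcl1, a chemokine that attracts neutrophils, had no UMI in set D monocytes and 177 ± 51.3 CPM in set E. The set E value is 47.2-fold a floor of 3 counts in the summed set D UMIs. Set D 2 and set D 3 held 38 and 72 monocytes. Controls 2 and 3 were at 8.08 and 91.6 CPM for Cxcl1, a spread between libraries that the floor leaves out. Nr4a1, an immediate early nuclear receptor, measured 482 ± 31.6 CPM in set D monocytes and 1417 ± 289 in those of set E. In neutrophils Marcksl1, an actin-regulating protein (chromosome 4, 129513581 to 129515985, plus strand), measured 176 ± 75.5 CPM in set D and 1404 ± 281 in set E, with controls at 230.3 ± 31.8 (log2 difference -3.07 ± 0.34).

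In adventitial fibroblasts Dpp4, a cell surface peptidase, was higher in set D at 102 ± 46.0 CPM against 1.61 ± 2.79 in set E (log2 difference 5.60 ± 0.94), as was Efhd1, a mitochondrial calcium-binding protein, at 51.7 ± 26.9 against 2.38 ± 4.12. Kcnj8, a potassium channel subunit, was lower at 12.8 ± 10.3 against 96.5 ± 48.6 CPM. Alkal2, Serpina3m and Bdkrb1 there, Tnf and Vasp in neutrophils, and Stmn1, Trp53inp1, Frat2, Fpr1 and Tnf in monocytes passed the mean natural log test alone, with Tnf at 52.1 ± 38.4 CPM in set D neutrophils and 786 ± 226 in set E. Limma called 166 of 6848 genes in adventitial fibroblasts (149 higher in set D, 17 lower), against 46 (33 and 13) on log2 CPM and 37 (31 and 6) by both. The count was 514 without control 1 and 17 without set E 3. In this class set D was the deeper group, at median UMIs per cell of 5810, 5418 and 4516 against 3754, 2707.5 and 2575 in set E. At resolution 2.0 the medians were 5850.5, 6311 and 4556 in set D and 5937.5, 7364 and 6966 in set E. The mean natural log test made false set calls in this class when simulated at the real depths. In monocytes limma called 69 of 7003 (11 and 58), against 18 (1 and 17) and 17 (1 and 16), with 25 without set E 3. At resolution 2.0, where control 1 entered the class with 485 cells, the count was 2. Of the monocyte genes named for this comparison Il1b passed there, while Cxcl1, Nr4a1, Stmn1, Trp53inp1, Frat2, Fpr1, Tnf and Ccl2 missed the threshold. In neutrophils it called 4 of 3525 (0 and 4), against 2 and 2, with 1 without set D 1 and 75 without set E 1. In T cells, B cells, alveolar macrophages, alveolar fibroblasts and interstitial macrophages limma called 0 genes on both scales, with 439, 301, 366, 501 and 592 at an unadjusted p under 0.05. Among the genes with the smallest p-values there were Gstp1 in B cells, Egr1 and Ppp1r15a in alveolar macrophages, Peg3 in alveolar fibroblasts and Mgst1 and Akr1b8 in interstitial macrophages, with Egr1, an immediate early transcription factor, at 842 ± 155 and 2328 ± 266 CPM. Without control 1 the counts were 35, 8, 25, 0 and 12. Median-of-ratios scaling moved the median log2 difference of all genes in neutrophils from 0.15 to -0.19, beyond which the difference of Marcksl1 lies.

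Immediate early genes, which also answer to tissue dissociation, were called lower in set D in 7 of 8 classes and on all 3 scales in 6, with Nr4a1 in monocytes the member past both tests and up to 10 of 15 members (monocytes) lower adjusted over the list alone. With an estimated correlation limma's camera gave an adjusted p = 0.523 or above for these calls. Inflammatory cytokines were called lower in set D in neutrophils, alveolar macrophages, monocytes and adventitial fibroblasts, with 7, 8, 9 and 4 members lower adjusted over the list alone and 3 past both tests, all in monocytes (Il1b, Il1a and Cxcl1), and with an adjusted p = 0.523 with an estimated correlation for each by limma. Ccl2, a chemokine that attracts monocytes, ran the other way in monocytes at 489 ± 90.1 CPM in set D and 222 ± 111 in set E, and passed the mean natural log test alone. Called lower in set D were also NRF2 targets (alveolar and interstitial macrophages, alveolar fibroblasts), heat shock (T cells, interstitial macrophages, both fibroblast classes), hypoxia and glycolysis (neutrophils, T cells), endothelial activation (alveolar macrophages, monocytes, adventitial fibroblasts), unfolded protein response (alveolar macrophages, adventitial fibroblasts), iron and ferroptosis (adventitial fibroblasts) and mitochondrially encoded transcripts (monocytes). For these calls limma's camera gave an adjusted p = 0.374 with an estimated correlation or above. Cxcl1, shared with the cytokine list, was the member of the endothelial list past both tests. Called higher in set D were the glucocorticoid response (both macrophage classes, adventitial fibroblasts), interferon response (T cells, interstitial macrophages), extracellular matrix (alveolar fibroblasts) and surfactant genes (alveolar macrophages), while MHC class II and nuclear oxidative phosphorylation went both ways between classes. For these calls limma's camera gave an adjusted p = 0.523 with an estimated correlation or above. Members lower adjusted over the list alone reached 6 of 17 NRF2 targets in interstitial macrophages and 6 of 11 hypoxia genes in neutrophils. Of 130 tests 41 were called and 33 on all 3 scales, and 24 were called without set D 1. The 8 calls lost on another scale were, with the limma adjusted p on log2 CPM, immediate early genes (0.0778) and MHC class II (0.0505) in B cells, surfactant (0.0511) and oxidative phosphorylation (0.0583) in alveolar macrophages, extracellular matrix (0.0642) and oxidative phosphorylation (0.0583) in alveolar fibroblasts, and glucocorticoid response (0.0778) and oxidative phosphorylation (0.0922) in adventitial fibroblasts. Single libraries carried several calls. In T cells the interferon gene Ifit3 was at 87.4, 88.01 and 17.6 CPM in set D and 34.2, 7.84 and 7.48 in set E, and in interstitial macrophages Isg15 was at 179.5 and 48.1 in set D 2 and set D 3 and 26.5, 13.9 and 41.7 in set E. The heat shock gene Hspa1a was in T cells at 44.1, 169 and 57.4 CPM in set D and 44.6, 513 and 455 in set E, and in alveolar fibroblasts at 414 and 225 in set D 2 and set D 3 and 281, 1391 and 1680 in set E. In all 4 classes with a heat shock call set E 1 lay below set D 2 for Hspa1a. Col3a1, a collagen chain, was in alveolar fibroblasts at 1375 and 1683 CPM in set D 2 and set D 3 and 2764, 292 and 496 in set E, so set E 1 ran against the matrix call. Calls that ended with a library left out are given with the limma adjusted p. In T cells immediate early genes ended without set D 1 (0.0733), set D 2 (0.150) or set E 2 (0.156). In B cells they ended without set D 1 (0.0782), set D 2 (0.102) or set E 2 (0.215), MHC class II without set D 1 (0.656), set E 2 (0.0855) or set E 3 (0.113) and oxidative phosphorylation without set D 1 (0.203) or set E 2 (0.116). In alveolar macrophages NRF2 targets ended without set D 2 (0.0516), MHC class II without set D 3 (0.0551) and endothelial activation without control 1 (0.0765) or set D 2 (0.0610). There the unfolded protein list ended without set D 1 (0.0554), set D 3 (0.111), set E 1 (0.0811) or set E 2 (0.0676) and surfactant without set D 3 (0.487), set E 1 (0.0607) or set E 2 (0.213). Oxidative phosphorylation ended there without set D 1 (0.0714), set D 3 (0.0541), set E 2 (0.116) or set E 3 (0.222). In alveolar fibroblasts NRF2 targets ended without set D 2 (0.229) or set E 1 (0.134), heat shock without set D 3 (0.302), set E 2 (0.213) or set E 3 (0.284) and immediate early genes without set E 3 (0.0565). There extracellular matrix ended without set D 3 (0.0968), set E 2 (0.132) or set E 3 (0.107) and oxidative phosphorylation without set D 2 (0.169) or set E 1 (0.362). In interstitial macrophages the interferon call ended without set D 2 (0.543) or set E 2 (0.0676), heat shock without set D 3 (0.484), set E 2 (0.137) or set E 3 (0.284), immediate early genes without set D 3 (0.0805) or set E 3 (0.113) and MHC class II without set D 2 (0.0829) or set E 1 (0.0607). In monocytes mitochondrially encoded transcripts ended without set D 2 (0.105) or set D 3 (0.132). In adventitial fibroblasts the glucocorticoid call ended without set E 1 (0.0789) or set E 3 (0.0565), the unfolded protein call without set E 1 (0.0762) and oxidative phosphorylation without set D 3 (0.0556) or set E 1 (0.189). In alveolar fibroblasts, interstitial macrophages and monocytes a left-out set D library leaves 1 in its group, assumed to vary like the others. With an estimated correlation 0 were called (adjusted p = 0.374 or above by limma's camera, 10 with an unadjusted p under 0.05). The smallest adjusted p by limma's camera was 0.05002 for the transitional epithelial, 0.0571 for the granulocyte and immunoglobulin, 0.345 for the p53 and 0.842 for the cell division list.

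Set D also held fewer cells of several classes than set E. Neutrophils made up 14.8% ± 11.7 of set D and 40.2% ± 5.97 of set E (controls 15.6% ± 4.87), general capillary endothelial cells 0.215% ± 0.238 and 8.77% ± 2.28 (controls 3.42% ± 2.33). AT2 epithelial cells, which make surfactant, made up 0.0557% ± 0.0483 and 2.17% ± 1.35, and classical monocytes 0.455% ± 0.315 and 5.32% ± 3.73. T cells went the other way, at 15.6% ± 2.10 and 6.77% ± 1.44. In each of these classes all libraries of one set lay beyond all of the other, which gives an exact permutation p of 0.10, the smallest that 3 against 3 allows, and an adjusted p of 0.173, so the design cannot reach the threshold. Limma on log-odds of the shares called 4 classes lower in set D, namely AT2 epithelial, general capillary and aerocyte endothelial cells and nonclassical monocytes. T-lineage clusters kept out of the T cell class held 47.7% of the cells of set D 1 and 25.8% of set D 2, against 0 to 0.162% elsewhere, and lower every other share in those libraries.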

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

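The depth test of control 1, the test of a diquat effect shared by all diquat libraries and the choice of these 3 patterns came after the results were seen. Genes called between the diquat sets numbered 4 in neutrophils, 69 in classical monocytes (2 at resolution 2.0, where control 1 entered the class) and 166 in adventitial fibroblasts by limma on mean natural log values, although both sets carry the same treatment label. By both tests they numbered 2, 17 and 37. In simulated neutrophils at the real depths the mean natural log test called 12.2 genes on average between sets that did not differ. T-lineage clusters outside the T cell class held 47.7% of the cells of set D 1 and 25.8% of set D 2, against 0 to 0.122% in controls.

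Control 1 stood apart from the other libraries in every class where it was tested. A difference in depth is argued against, since with as many cells per library, each thinned to 1000 UMIs, its median correlation with the others stayed below that of every other library by more than their SD in 7 of 7 classes (in T cells 0.879 against 0.956 to 0.978). In control 1, 153 genes of at least 10 CPM in each of the other 8 libraries had no UMI. Another library lacked at most 1 such gene, and 124 genes were present in control 1 alone. Some of the 124 are older symbols of lacking genes, in pairs chosen here after their values were seen. Septin1 and H2az1 were at 0 in control 1, where Sept1 and H2afz, at 0 elsewhere, were at 113.9 and 371.6 CPM. A candidate explanation that gives such pairs is counting against another gene annotation. Genes with no UMI in control 1 were not taken out of the tests. The values of control 1 also rose with gene length, with a median rank correlation across genes of 0.691 between gene span and control 1 minus the other controls (genes are not independent replicates), so intronic reads or more nuclear RNA may contribute, and these explanations can hold together. No biological explanation was tested.

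The T-lineage clusters of set D 1 and set D 2 held cells with a UMI of Rag1 (52.7%) and Dntt (50.5%), genes of receptor rearrangement, against 0 and 0.517% of T cells in the other libraries and 0.362% and 0.241% of B cells, at median depths of 2359 UMIs in the clusters and 5059 in those T cells. An effect of diquat shared by the diquat libraries is argued against, since of all cells, whatever their cluster, under 1% held a UMI of Rag1 or Rag2 in 4 of 6 diquat libraries (0.0649% in set D 3 and 0 in set E, against 24.3% and 17.9% in set D 1 and set D 2 and at most 0.144% in controls). Carry-over of thymic tissue may be the source and stays open. Rag2 had a UMI in 11.4% of the cells but Ptcra in 4.1%, under the 10% set beforehand. The same clusters held 0.162% of the cells of set D 3.

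Neutrophils of set E carried on average more transcripts of the inflammatory cytokine list than those of set D, at 54250 ± 17960 against 31230 ± 7312 CPM, although set E 1 (35040) lay below set D 2 (36380). With neutrophils thinned to 1000 UMIs, leaving out 0 to 18 shallower cells per library, the list gave 57.3 ± 17.1 UMIs per cell in set E and 34.9 ± 8.65 in set D (24.6 ± 3.99 in controls), against 297.6 and 84.2 without thinning. The ratio after thinning was 1.64, so the difference in means remained at equal depth. Set E 1 (38.8) lay below set D 3 (40.5), however. The test set beforehand asked for no such overlap, so it cannot decide on a difference in depth. The immediate early list was higher in set E in 8 of 8 tested classes, also on log2 CPM, so a dissociation response of set E may contribute. The biological difference between the sets, which the labels do not describe, stays open and was not tested.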

How the results depend on the processing

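Alternatives chosen after the data were seen were log2 CPM with and without median-of-ratios factors, voom, removal of cells with the highest 5% of doublet scores, control 1 left out on log2 CPM, control 1 and set D 1 left out together, T-lineage clusters moved into the T cell class or out of the denominator, and limma on log-odds of shares. Of 513 alternative values of class shares, 464 kept direction and side of the threshold, 13 moved past it and 36 reversed, none of these past the threshold. Between the sets the permutation test has a smallest p of 0.10, so its alternatives could not move past the threshold whatever the data. Of 5958 alternative values of named genes, 5175 kept both, 581 fell short of the threshold, 185 moved past it and 17 reversed. The cause of each change below was not tested unless stated. Planned count models, namely DESeq2 and its size factors and the edgeR test of shares, were not run. The plan replaced count models where the matrix held log values, but the recovered UMIs and the cell counts would have allowed them. The stricter cell filter was not run because it removes 0 cells. Both tests together recovered 5.06% (neutrophils) and 2.92% (adventitial fibroblasts) of simulated 1.5-fold changes at the real depths and 6.98% and 3.11% at equal depths.

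Without the filter on low values, which adds genes to the adjustment, the mean natural log counts with diquat were 46 in neutrophils, 2 in T cells, 7 in B cells, 2 in alveolar macrophages, 0 in alveolar fibroblasts, 1 in interstitial macrophages, 0 in monocytes and 18 in adventitial fibroblasts. Between the sets they were 1 in neutrophils, 1 in B cells, 0 in monocytes and 7 in adventitial fibroblasts. Set D minus control gave 68 genes in neutrophils, 5 in alveolar macrophages, 22 in alveolar fibroblasts, 6 in interstitial macrophages and 276 in adventitial fibroblasts. Set E minus control gave 60 in neutrophils, 2 in T cells, 1 in alveolar macrophages, 21 in alveolar fibroblasts, 7 in interstitial macrophages and 25 in adventitial fibroblasts. At resolution 2.0, where control 1 entered the class with 485 cells, monocytes gave 38 with diquat and 2 between the sets, and adventitial fibroblasts 262 and 80. The fit on set D and set E alone gave 55 in neutrophils, 23 in T cells, 1 in B cells, 8 in alveolar macrophages and 324 in adventitial fibroblasts. With thinned summed UMIs the diquat counts were 19 in T cells, 2 in B cells, 17 in alveolar macrophages, 74 in interstitial macrophages and 33 in monocytes. The set counts were 2 in neutrophils, 1 in T cells, 20 in monocytes and 63 in adventitial fibroblasts.

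On log2 CPM the diquat counts were 20 in T cells, 1 in B cells, 23 in alveolar macrophages and 12 in monocytes, and the set counts 2 in neutrophils, 18 in monocytes and 46 in adventitial fibroblasts. With median-of-ratios factors they were 1 in B cells, 17 in alveolar macrophages, 56 in interstitial macrophages and 17 in monocytes, and between the sets 2 in neutrophils, 19 in monocytes and 51 in adventitial fibroblasts. With voom they were 62 in neutrophils, 17 in T cells, 102 in alveolar macrophages, 153 in alveolar fibroblasts and 33 in monocytes. Between the sets they were 2 in neutrophils, 3 in monocytes and 45 in adventitial fibroblasts. On log2 CPM without control 1 they were 63 in neutrophils, 76 in T cells, 12 in B cells, 137 in alveolar macrophages, 254 in alveolar fibroblasts and 155 in interstitial macrophages. Between the sets they were 11 in neutrophils, 17 in T cells, 9 in B cells, 10 in alveolar macrophages and 4 in interstitial macrophages. Without control 1 and set D 1 they were 26 in neutrophils, 12 in T cells, 18 in B cells, 211 in alveolar macrophages and 234 in adventitial fibroblasts. Between the sets they were 1 in neutrophils, 9 in alveolar macrophages and 342 in adventitial fibroblasts. With the highest doublet scores removed they were 18 in alveolar macrophages, 198 in alveolar fibroblasts and 143 in monocytes, and 38 in monocytes between the sets. This also took control 1 (27 cells) out of the alveolar fibroblasts and set D 2 (23 cells) out of the monocytes, leaving 1 set D library there, and leaving out these libraries alone gave 236 and 149 with diquat and 29 in monocytes between the sets. Gene lists called numbered 0 and 0 with an estimated correlation (smallest adjusted p 0.0529 and 0.374, limma) and 4 between the sets by fry. Limma on log-odds called 1 class share with diquat and 4 between the sets.

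The correlations of same-numbered deviations over 51 pairs ran from -0.333 to 0.371 with a median of 0.0646. Set D 1 with set E 1 gave 0.227 to 0.371 and set D 2 with set E 2 gave 0.0878 to 0.296. Set D 3 with set E 3 gave -0.231 to 0.0968, and pairs with a control -0.333 to 0.223. Differently numbered pairs were not computed, so these values cannot decide whether replicate numbers pair the libraries. With the replicate number as a block the diquat counts were 21 in neutrophils, 1 in alveolar macrophages, 1 in alveolar fibroblasts, 1 in interstitial macrophages and 204 in monocytes. With this block the set count was 189 in monocytes, and limma on log-odds with the block called 1 share with diquat and 7 between the sets. The block moved no other count past 1.5 times.

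Leaving out each library in turn, the diquat count ran from 22 to 418 in neutrophils (23 without control 2, 418 without control 3, 22, 53 and 25 without set D 1, set D 2 and set D 3, 41 and 30 without set E 2 and set E 3). It ran from 2 to 39 in T cells (39 without control 1, 8 without control 3, 2 without control 2, set D 1, set D 3 or any set E library) and from 0 to 27 in B cells (21 without control 1, 27 without control 3, 1 without set D 2). It ran from 2 to 209 in alveolar macrophages (209, 2 and 6 without controls 1, 2 and 3, 3 and 4 without set D 1 and set D 3, 3, 4 and 2 without set E 1, set E 2 and set E 3). It ran from 0 to 295 in alveolar fibroblasts (236, 0 and 34 without controls 1, 2 and 3, 20 and 0 without set D 2 and set D 3, 295, 17 and 10 without set E 1, set E 2 and set E 3). It ran from 0 to 170 in interstitial macrophages (170, 2 and 2 without controls 1, 2 and 3, 0 without set D 2 or set D 3, 1 without set E 2 or set E 3). The range was 18 to 149 in monocytes (18 and 146 without controls 2 and 3, 149 without set D 2, 40, 26 and 37 without set E 1, set E 2 and set E 3) and 19 to 180 in adventitial fibroblasts (180, 19 and 66 without controls 1, 2 and 3, 37 without set D 3, 37 and 40 without set E 2 and set E 3). In monocytes a left-out control or set D library, and in alveolar fibroblasts and interstitial macrophages a left-out set D library, leaves 1 library in its group, which is then assumed to vary like the others.

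Between the sets the count ran from 1 to 75 in neutrophils (31 and 23 without controls 1 and 3, 1, 1 and 2 without set D 1, set D 2 and set D 3, 75, 2 and 2 without set E 1, set E 2 and set E 3). It ran from 0 to 35 in T cells (35 without control 1, 1 without set D 3 or set E 1), from 0 to 8 in B cells (8 without control 1). The range was 0 to 25 in alveolar macrophages (25 without control 1, 1 without set D 1, 18 without set E 1), 0 to 1 in alveolar fibroblasts (1 without set D 2) and 0 to 12 in interstitial macrophages (12 without control 1). It ran from 25 to 101 in monocytes (29 and 39 without set D 2 and set D 3, 26 and 25 without set E 2 and set E 3) and from 17 to 514 in adventitial fibroblasts (514 without control 1, 51 and 35 without set D 1 and set D 3, 49, 27 and 17 without set E 1, set E 2 and set E 3). Called lists ran from 20 to 39 with diquat and from 24 (without set D 1) to 44 between the sets, and class shares stayed at 0. Between the sets the permutation test of shares could give no other count.

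Reversed shares, none past the threshold, were as follows, in percentage points except on log-odds. Within its compartment the diquat difference was -3.14 for AT2 cells, -1.98 for aerocytes, -12.2 for general capillary cells and -0.492 for mesothelial cells. The set difference was 7.96 for club cells, -0.10 for ILC2 and 2.35 for mesothelial cells. The club cell difference was 0.0497 at resolution 2.0 and 0.0338 with the T-lineage clusters out of the denominator. On log-odds, with and without the block, the diquat difference was -0.950 for AT2 cells, -0.645 for aerocytes, -0.872 for general capillary cells, -0.136 for ILC2 and -0.0865 for mesothelial cells. The set difference was -0.355 for ILC2. With each library left out, diquat differences ran from -0.138 to 0.582 (AT2), -0.0245 to 0.340 (aerocyte), -0.0695 to 0.0933 (club), -0.264 to 1.96 (general capillary), -0.0765 to 0.212 (ILC2) and -0.648 to 0.259 (pericyte). Set differences ran from -0.234 to 0.488 (ILC2) and -0.476 to 0.0476 (mesothelial).

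Reversed differences of named genes, none past the threshold, were near 0 in the main test. On thinned UMIs they were -0.22 for Klf9 in B cells with diquat, 0.12 for Fasn in alveolar macrophages between the sets and -0.0241 for Atf4 in adventitial fibroblasts between the sets. Atf4 gave -0.0137 at resolution 2.0. Fasn gave 0.0295 on log2 CPM with or without control 1 and 0.0336 with median-of-ratios factors. Ndufs1 in alveolar macrophages between the sets gave 0.00019 with these factors and 0.0395 with voom. Ctsh in adventitial fibroblasts with diquat gave -0.0348 with voom and -0.0072 on log2 CPM without control 1. With each library left out, Klf9 in B cells ran from -0.0114 to 0.0411 with diquat. Between the sets Scd1 ran from -0.185 to 0.0172 and Fasn from -0.0239 to 0.0057 in alveolar macrophages and Usp18 from -0.0182 to 0.0816 in interstitial macrophages.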

Other observations

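The counts of other splits of the libraries were chosen after the gene counts were seen. B cells made up 22.8% ± 3.30 of control cells, 16.8% ± 13.7 in set D and 5.20% ± 1.30 in set E, with 5 of 6 diquat libraries below all controls and an exact permutation p of 0.119 (adjusted p 0.520). Alveolar macrophages ranged in set D from 0.614% to 24.4% of cells, against 4.86% ± 3.87 in controls and 5.67% ± 1.03 in set E. Alveolar fibroblasts made up 9.40% ± 5.32 of set E, 2.68% ± 3.76 of set D and 2.13% ± 1.55 of controls.

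The libraries were split at random into groups of the same sizes, the real split included. The share of splits with as many genes was under 0.05 for 6 of the 7 diquat counts tested. These shares were not adjusted over the classes, so chance is not excluded. In alveolar and adventitial fibroblasts another split gave more genes than the real one. That of the alveolar fibroblasts still set all controls against all diquat libraries, so it cannot show what chance alone gives. Classical monocytes (83 genes with diquat, 69 between the sets), with 2 controls and 2 set D libraries, were not tested this way. As many genes came from 1 of 100 splits in neutrophils (109 real, highest other 33), 1 in T cells (4, highest other 2), 1 in alveolar macrophages (11, highest other 7), 2 in alveolar fibroblasts (59, highest other 61), 1 in interstitial macrophages (36, highest other 35) and 3 in adventitial fibroblasts (116, highest other 242), while in B cells, where the real count was 0 and the highest other 1, all 100 splits gave as many whatever the data. The split with 242 genes set the set D libraries against the rest, which points to a structure of the samples. In neutrophils the split with 33 genes set the set E libraries against the rest. In T cells, alveolar fibroblasts and interstitial macrophages the highest other split kept the controls together and mixed the diquat sets. Between the sets the 10 splits are too few for a share under 0.05. The real counts were 4 in neutrophils (1 of 10 splits as large, highest other 0) and 166 in adventitial fibroblasts (1 of 10, highest other 0), and 0 in T cells, B cells and alveolar macrophages (10 of 10, highest other 0).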
